A study of Mus musculus with 24 samples.

How the data were processed

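Hepatic RNA of male Abcb4 knockout mice (FVB.129P2-Abcb4tm1Bor/J) and of FVB/NJ wild type controls was measured on 24 arrays with 2 colours, 6 at each of 3, 6, 9 and 20 weeks. Per the labels, total RNA was extracted with a Qiagen RNeasy protocol, labelled with Cy5 and Cy3 by a Stratagene FairPlay kit and hybridised to spotted cDNA arrays, with both genotypes on each array. Whether the probes are cDNA or oligonucleotides was not settled from the annotation, which bears on how far members of a gene family cross-hybridise. One label counts the weeks from weaning, and the source names give 3 weeks for all arrays, so the week was taken from the array titles. The values used are the authors' deposited table of 1 log ratio per feature and array; the labels do not give its log base. It was treated as log2, and the deposited values reach from -8.45 to 7.53, which as log10 would be ratios beyond the range of a scanner; a natural logarithm is not excluded. No fold changes were computed from it. Background correction, normalization within arrays and filters are not given in the sources used here. No value was missing, and 0 other columns of per-sample values were present. Array medians lay between -0.037 and 0.015 before further steps. Signal over background is not analysed here, so weak features were not told from strong ones, and the number of arrays limits the precision.

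The direction of each ratio came from the dyes in the labels and from the signs of the arrays. Within a week, arrays of opposite dye orientation correlated with a median r of -0.29, -0.47, -0.51 and -0.35 at 3, 6, 9 and 20 weeks, so the values had not been turned to 1 direction. That the table holds Cy5 over Cy3 is likely rather than stated, and rests on taking the Abcb4 feature as lower in the knockout. The lower Abcb4 values are therefore an assumption and not a result, and with Cy3 over Cy5 every rise and fall would be exchanged. Whether the probe lies in the deleted part is unknown. Arrays with wild type RNA in Cy5 were turned in sign, so that positive values mean higher in the knockout.

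Features were named through the platform annotation in use here. Joining value numbers and probe numbers directly put unrelated values under one accession: over 48 accessions spotted 10 or 11 times, the mean of the median correlation between copies was 0.0178. Among 792 layouts and offsets tried, reading the array grid by column with both axes reversed gave 0.691, and the next best gave 0.0276. A median r above 0.5 was reached by 0 of the 48 accessions in the direct join. In the column layout 33 of the 48 reached it, and the others did not. In that layout the Abcb4 feature averaged -1.31 and had one sign on 24 of 24 arrays, whereas in the direct join it averaged -0.019 and lay below 0 on 12. This layout was settled after the values had been seen, by agreement between copies, and every gene name rests on it. A single gene was named for 18218 features, several genes for 16 and none for 4341; 43 features had a gene identifier outside the reference table (mouse assembly GRCm38.p6, used for names and neighbours only), and 0 symbols changed. More than 1 feature represented 1193 genes. Their features were averaged per array, and among them 2, 13, 23 and 10 genes at 3, 6, 9 and 20 weeks had features passing in opposite directions. Probes of the Cyp2a, Cyp2c, Cyp3a, Cyp4a, Ces1, Gstm, Hsd3b, Mup and amylase families can bind transcripts of close relatives, so values of single members of these families are uncertain.

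Each array was centred on its median. A linear model with 1 mean per week and 1 dye-orientation term common to all weeks was fitted to all 24 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3; 20861 items were tested, 16504 named genes and 4357 features without a single gene. The adjusted p threshold was 0.05 (Benjamini-Hochberg), with values required on at least 4 of 6 arrays in every week. A dye effect was found for 2409 of the items (11.6%), and the median residual SD was 0.147 with the dye term and 0.156 without. Differences between weeks were tested with the moderated F test and with contrasts of 6, 9 and 20 against 3 weeks, and changes common to the time course with the mean of the 4 weekly means. SDs are those of the 6 centred and turned arrays of a week.

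The genes to be named were fixed by a rule. At each week these were the 8 largest rises and 8 largest falls among genes past the threshold with 1 sign on every array, and up to 4 members with the smallest p of each gene list, along with Abcb4 and the 10 genes with the largest range of weekly means past the F test. Clone names and predicted genes were counted but not named. The rule allows 438 gene and week results, and the text names 241 of them. This choice was made after the values were seen and favoured sturdy calls: of 65 results whose call ended when 1 array was left out, 63 are not named, and of 109 that ended under any alternative or with 1 array left out, 85 are not named. The named genes are therefore sturdier than those the rule allows. The 30 lists were extracellular matrix, matrix remodelling, stellate cell and myofibroblast, cholangiocyte, macrophage, neutrophil, lymphocyte, endothelial, chemokine and cytokine, acute phase, bile acid synthesis and regulation, hepatobiliary transporter, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, phase I metabolism, phase II and antioxidant, male-biased liver, female-biased liver, cell cycle, oncofetal and tumour-associated, hepatocyte, MHC class II, interferon-induced, endoplasmic reticulum stress, lysosome, erythroid, exocrine pancreas, adipose, and Abcb4 neighbours on chromosome 5. Each list was tested per week with limma's camera (two-sided, preset correlation between genes of 0.01, adjusted over lists and weeks), again with an estimated correlation, and with fry, whose p tests whether a list moves on balance in 1 direction. List medians are over the weekly means of the measured members.

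The fit was tested on simulated data for the 9-week comparison, with 20861 genes of which 200 were changed. Of 50 genes each, it recovered 21 changed by 0.25 on the log2 scale, 43 by 0.5, 48 by 1 and 50 by 2. Of the unchanged genes 11 were called, and with the 34 extracellular matrix genes shifted by 0.2, 1 list was called. The simulated noise was independent between genes and between arrays. It therefore does not test error rates with repeated mice or with correlated genes. In the real data the estimated correlation within the extracellular matrix list was 0.29.

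Alternatives were no centring, scaling to a common median absolute value (limma's normalizeMedianAbsValues, the function its scale option applies to log ratios), quantile normalization, no dye term or 1 dye term per week, weeks fitted on their own, missing-value filters, features tested singly, robust empirical Bayes, array weights, averaging the closest pair of opposite dye orientation in each week, the sample number as a block, an adjusted p under 0.01, and leaving out each array in turn. With no missing value, the filters change nothing and test nothing. Alternatives added after the data were seen were testing only features with 1 gene and leaving out replicates 1 and 2 of 3 weeks together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and the layout was worked out with numpy 2.4.6 and pandas 2.3.3.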

Results

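Liver RNA of male mice lacking Abcb4, the canalicular phospholipid transporter that moves phosphatidylcholine into bile, was compared with that of wild type FVB/NJ mice on 2-colour arrays, spotted cDNA arrays per the labels, at 3, 6, 9 and 20 weeks. Each of the 24 arrays held knockout RNA in one dye and wild type RNA in the other, with 6 arrays per week and 3 in each dye orientation. The series states 5 mice per genotype and week and 1 dye swap, but not which arrays repeat a pair. At least 1 of the 6 arrays of a week therefore repeats mice, so p-values count more arrays than mice and rest partly on technical spread. Weeks were taken from the array titles. Values are log2 ratios of knockout over wild type, given as mean ± SD over the 6 arrays of a week; log base 2 is an assumption, since the labels do not state it. The sign of every ratio is an assumption too: it was set so that Abcb4 is lower in the knockout, and with the other sign each rise given here would be a fall and each fall a rise. Tests are limma's moderated tests with Benjamini-Hochberg adjustment over 20861 genes and unnamed features, two-sided. Genes ranked by size are named genes with one sign on all 6 arrays of the week; some unnamed features changed more and were counted but not named. The number of arrays limits the precision. The tests of the comparisons, the gene lists and the rule for naming genes were fixed before the data were examined, whereas the tests of the patterns on single arrays that are weighed at the end were chosen after those patterns were seen. Which of the genes that rule allows are named was chosen after their values were seen, and most of those whose call depends on 1 array were not named; the match between value numbers and probes was settled from the data as well.

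Abcb4 had one sign on each of the 24 arrays, which was taken as lower in the knockout and set the sign of all ratios, with means of -0.87 ± 0.24 at 3 weeks, -1.57 ± 0.37 at 6 weeks, -1.42 ± 0.66 at 9 weeks and -1.34 ± 0.34 at 20 weeks. Whether its probe lies inside the part deleted in the knockout is unknown. Genes past the threshold numbered 1542 at 3 weeks (759 higher and 783 lower), 4362 at 6 weeks (2252 and 2110), 4444 at 9 weeks (2169 and 2275) and 2807 at 20 weeks (1687 and 1120). Which direction held more genes depended on the scaling at 3, 6 and 9 weeks: the share that was higher was 49.2, 51.6 and 48.8%, against 53.9% at 3 weeks with quantile normalization, 45.4% at 6 weeks without centring and 50.1% at 9 weeks with a common spread. At 20 weeks higher genes were the majority under all 4 settings, with 60.1% here and at the least 53.7%, without centring. At all 4 weeks 400 genes passed in one direction, 306 higher and 94 lower, among them Anxa5, Lcn2, Ly6e, Ifi27l2b, Col3a1 and Cd74 on the higher side and Cyp27a1, Cyp2e1 and Cyp2c38 on the lower side. At least 1 week had a call for 7365 genes, and 70 genes passed in opposite directions at 2 of the weeks. Leaving out replicate 2 at 20 weeks lowered the count of that week to 1821. Fitting each week on its own gave 525 genes at 3 weeks and 2286 at 9 weeks, and scaling arrays to a common spread gave 2480 at 3 weeks.

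**Figure D1:**
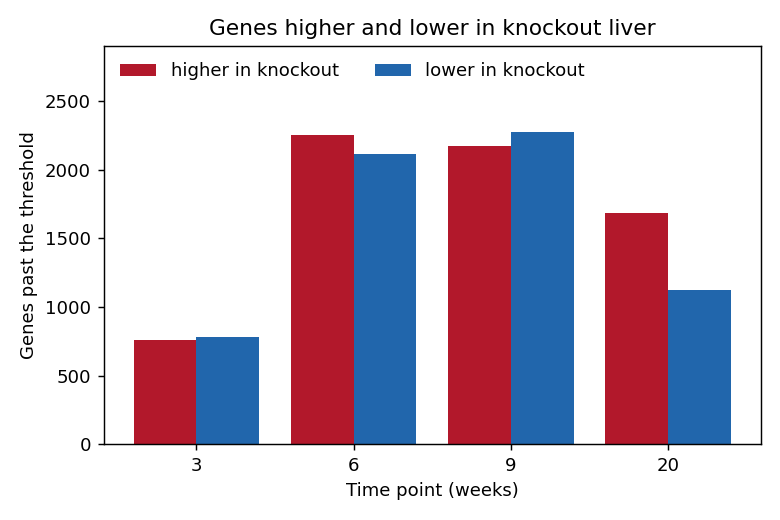
Number of genes past an adjusted p of 0.05 at each time point (weeks, horizontal axis), higher (red) and lower (blue) in knockout liver than in wild type liver, from 6 arrays per week. Genes past the threshold number 1542 at 3 weeks, 4362 at 6 weeks, 4444 at 9 weeks and 2807 at 20 weeks, both directions together.

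The first comparison asked how knockout liver differed from wild type liver at the earliest time, 3 weeks. Among the largest rises were Clu, a secreted chaperone, Anxa5, a phospholipid-binding annexin, Ly6e and Lcn2, an iron-siderophore-binding protein. Their means were Clu (3.11 ± 0.40), Anxa5 (2.63 ± 0.41), Ly6e (2.49 ± 0.66) and Lcn2 (2.48 ± 1.79), each positive on 6 of 6 arrays, with adjusted p of 1.00e-10, 2.95e-09, 1.72e-11 and 7.37e-04. The epithelial keratin Krt8 (2.29 ± 0.46), the interferon-responsive Ifi27l2b (2.23 ± 0.51) and the glutathione transferases Gstm6 (2.19 ± 1.16) and Gstm3 (2.16 ± 0.66) rose as well. The largest falls were in Eif4ebp3 (-2.84 ± 1.28), Cyp2a4 (-2.78 ± 1.07), Wfdc21 (-2.74 ± 1.43), Amy1 (-2.58 ± 1.42) and Amy2a5 (-2.50 ± 1.40), the last pair being amylases. Orm1, an acute phase protein, Thrsp, a regulator of fatty acid synthesis, and Cyp2c40, of the female-biased liver list, also fell (-2.41 ± 1.60, -2.10 ± 2.11 and -2.09 ± 1.36). With the 3-week arrays fitted on their own the calls of Lcn2 (0.13), Gstm6 (0.0554), Amy2a5 (0.0562), Thrsp (0.16) and Cyp2c40 (0.0716) ended, given with the adjusted p, and that of Thrsp also ended without replicates 1 and 2 together (0.37). Without this pair the mean of Thrsp was -0.86, so most of its fall lies on these 2 arrays, and those of Orm1 and Cyp2c40 were -1.56 and -1.29, both still past the threshold.

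Of the 34 measured extracellular matrix genes, 12 rose, 0 fell and 22 did not pass (15 up and 0 down adjusted over the list alone, camera adjusted p = 1.75e-12, adjusted p = 0.0541 with an estimated correlation). Nid1 (1.79 ± 0.69), Col3a1 (1.38 ± 0.51) and Col4a1 (1.05 ± 0.25) were among the rises. Here and at later weeks the camera adjusted p with an estimated correlation is printed only where it did not pass. For the called lists without it, that value lay between 0.00376 and 0.0460, often far above the one printed. For the 3-week cell cycle list it was 0.0246, against 1.77e-19 with the preset correlation of 0.01. Of the 22 measured stellate cell and myofibroblast genes, 5 rose, 0 fell and 17 did not pass (7 up and 0 down adjusted over the list alone, camera adjusted p = 5.22e-04, adjusted p = 0.0599 with an estimated correlation). Vim (0.77 ± 0.50) and Tgfbi (0.71 ± 0.34) were examples. The rises became 2 without replicate 1 and 3 without replicate 5 or 6. Of the 23 measured cholangiocyte genes, 7 rose, 0 fell and 16 did not pass (8 up and 0 down adjusted over the list alone, camera adjusted p = 6.15e-06, adjusted p = 0.0776 with an estimated correlation). Elf3 (1.31 ± 0.46) and Cdh1 (0.98 ± 0.55) were among them. Of the 27 measured macrophage genes, 9 rose, 0 fell and 18 did not pass (14 up and 0 down adjusted over the list alone, camera adjusted p = 1.45e-10, adjusted p = 0.0608 with an estimated correlation). Lyz2 (1.02 ± 0.45) and Mpeg1 (0.93 ± 0.41) rose. The rises became 2 without replicate 6, 3 without replicate 2, 4 without replicate 4 and 5 without replicate 1. Of the 7 measured MHC class II genes, 3 rose, 0 fell and 4 did not pass (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.00395, adjusted p = 0.0607 with an estimated correlation). Cd74 (2.13 ± 0.67) and H2-Aa (1.06 ± 0.54) rose; Cd74 is the invariant chain. Of the 20 measured interferon-induced genes, 5 rose, 0 fell and 15 did not pass (6 up and 0 down adjusted over the list alone, camera adjusted p = 8.66e-08). Bst2 (0.96 ± 0.36) and Psmb8 (0.79 ± 0.18) were examples. Of the 21 measured lysosome genes, 5 rose, 1 fell and 15 did not pass (8 up and 1 down adjusted over the list alone, camera adjusted p = 9.23e-04). The rises became 3 without replicate 4 or 6. Ctsb rose (0.73 ± 0.42) and Lamp2 fell (-0.54 ± 0.47). Of the 36 measured cell cycle genes, 16 rose, 0 fell and 20 did not pass (28 up and 0 down adjusted over the list alone, camera adjusted p = 1.77e-19). Stmn1 (1.20 ± 0.49) and Mki67 (0.55 ± 0.30) rose. Of the 15 measured oncofetal and tumour-associated genes, 8 rose, 0 fell and 7 did not pass (9 up and 0 down adjusted over the list alone, camera adjusted p = 2.03e-11). H19 (3.08 ± 2.37), Cd63 (1.27 ± 0.70) and Tff3 (1.21 ± 0.32) were among them. H19, an imprinted transcript of fetal liver, read 5.42, 4.73, 3.05, 0.00, 0.40 and 4.87 on replicates 1 to 6. Without replicates 1 and 2 together the means of H19 and Cd63 were 1.98 and 0.83, both past the threshold. Of the 24 measured hepatocyte genes, 1 rose, 10 fell and 13 did not pass (1 up and 11 down adjusted over the list alone, camera adjusted p = 4.02e-07). Apoc3 (-1.15 ± 0.53) and Apoh (-0.73 ± 0.54) fell, while transferrin, Trf, rose (1.23 ± 0.95). Calls that ended with the 3-week arrays fitted on their own, with the adjusted p, were those of Vim (0.11), H2-Aa (0.0575), Ctsb (0.0718), Lamp2 (0.20), H19 (0.15), Cd63 (0.0532), Apoh (0.0701) and Trf (0.0864). The Lamp2 call also ended with the closest pair averaged (0.0544).

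Of the 18 measured bile acid synthesis and regulation genes, 0 rose, 5 fell and 13 did not pass (1 up and 11 down adjusted over the list alone, camera adjusted p = 1.64e-09). Cyp39a1 (-1.35 ± 0.62), Slc27a5 (-1.34 ± 0.41) and Cyp27a1 (-1.23 ± 0.26) fell; Cyp27a1 is the sterol hydroxylase of the alternative pathway and Slc27a5 a bile acid ligase. Of the 21 measured phase I metabolism genes, 2 rose, 11 fell and 8 did not pass (3 up and 14 down adjusted over the list alone, camera adjusted p = 8.23e-07). Cyp2e1 (-1.01 ± 0.25) and Ces1d (-0.68 ± 0.29) fell, whereas Aldh1a1 (1.79 ± 1.25) and Cyp3a11 (1.70 ± 0.41) rose. Of the 29 measured phase II and antioxidant genes, 9 rose, 4 fell and 16 did not pass (10 up and 5 down adjusted over the list alone, camera adjusted p = 0.00283, adjusted p = 0.23 with an estimated correlation). Gstm1 (2.09 ± 0.69) and Ephx1 (adjusted p = 1.29e-05) rose and Gstt3 (-1.65 ± 0.59) fell. Of the 20 measured cholesterol synthesis genes, 0 rose, 5 fell and 15 did not pass (0 up and 8 down adjusted over the list alone, camera adjusted p = 1.19e-07, adjusted p = 0.17 with an estimated correlation). The falls became 2 without replicate 1, 2 or 3 and 9 without replicate 5. Tm7sf2 (-1.01 ± 1.09) and Ebp (adjusted p = 2.31e-05) fell. The list median was -1.78 and -1.70 on replicates 1 and 2 and lay between -0.16 and 0.24 on the others. Of the 25 measured acute phase genes, 5 rose, 9 fell and 11 did not pass (5 up and 11 down adjusted over the list alone, camera adjusted p = 0.00650, adjusted p = 0.38 with an estimated correlation). The list no longer passed without replicate 5 (adjusted p = 0.0571). Orm1, Apcs (-1.63 ± 0.40) and Serpina3n (-1.45 ± 0.64) fell, while Lcn2 and Cp (1.17 ± 0.33) rose. Of the 11 measured male-biased liver genes, 0 rose, 3 fell and 8 did not pass (0 up and 4 down adjusted over the list alone, camera adjusted p = 0.00509, adjusted p = 0.18 with an estimated correlation). Of the 17 measured female-biased liver genes, 3 rose, 7 fell and 7 did not pass (3 up and 8 down adjusted over the list alone, camera adjusted p = 0.00199). Cyp2a4 and Cyp2c40 were among the falls. Of the 11 measured exocrine pancreas genes, 0 rose, 1 fell and 10 did not pass (0 up and 2 down adjusted over the list alone, camera adjusted p = 2.23e-04, adjusted p = 0.28 with an estimated correlation). The list no longer passed without replicate 6 (adjusted p = 0.14). The falls became 2 without replicate 3, 4 or 6. The single fall was Amy2a5. On replicate 6 each of the 11 members lay below -1 with a list median of -4.21, and on no other array of the series did more than 1 member do so. By camera no call was made at 3 weeks for matrix remodelling (adjusted p = 0.34, median 0.03 but 0.01 without replicate 1), neutrophil (adjusted p = 0.24, median -0.03 but -0.06 without replicate 2 and 0.01 without replicate 5), lymphocyte (adjusted p = 0.11, median 0.02 but 0.04 without replicate 6), endothelial (adjusted p = 0.94, median -0.03 but -0.07 without replicate 6 and 0.03 without replicate 5), chemokine and cytokine (adjusted p = 0.11, passing at 0.0333 without replicate 3, median 0.03 but 0.02 without replicate 6 and 0.05 without replicate 3), hepatobiliary transporter (adjusted p = 0.41, median -0.02 but -0.04 without replicate 3 and 0.00 without replicate 5), fatty acid synthesis (adjusted p = 0.12, passing at 0.0297 without replicate 5, median -0.07 but -0.16 without replicate 5 and 0.00 without replicate 2), fatty acid oxidation (adjusted p = 0.49, median -0.03 but -0.06 without replicate 2 and 0.00 without replicate 5), endoplasmic reticulum stress (adjusted p = 0.18, median 0.13), erythroid (adjusted p = 0.29, median -0.21), adipose (adjusted p = 0.28, median 0.05 but -0.01 without replicate 2 and 0.08 without replicate 4) and Abcb4 neighbours on chromosome 5 (adjusted p = 0.12, median 0.01). Here and at later weeks the lowest or highest median with 1 array of the week left out is added where it changed sign or moved by over 1.5 times and differs at 2 decimals. Of these lists fry, which tests for movement in one direction and not against other genes, called neutrophil (0.0454), lymphocyte (0.0183) and adipose (0.0412), given with the adjusted p, and it did not call acute phase (0.0554) or exocrine pancreas (0.0510). The list medians of neutrophil, endothelial, fatty acid synthesis and adipose changed sign when 1 array of the week was left out. Within the lists without a camera call, Cxcl10 (1.12 ± 0.66), Ccl2 (0.85 ± 0.28), Mmp14 (0.73 ± 0.57) and the collagen chaperone Serpinh1 (0.72 ± 0.44) rose singly. Other members fell. Rises and falls past the threshold were 2 and 1 for matrix remodelling, and 3 and 0 each for lymphocyte and chemokine and cytokine. Neutrophil and endoplasmic reticulum stress had 0 and 1 each. Hepatobiliary transporter had 1 and 3, fatty acid synthesis 0 and 3, and fatty acid oxidation 2 and 3. Adipose had 1 and 0, the Abcb4 neighbours 4 and 1, and endothelial and erythroid none. Some counts moved with 1 array left out. Fitted on their own, the 3-week arrays gave no call for Aldh1a1 (0.10), Tm7sf2 (0.18), Ebp (0.0596), Cxcl10 (0.0716) and Mmp14 (0.15), and without replicates 1 and 2 together none was made for Tm7sf2 (0.26), Cxcl10 (0.0623), Ccl2 (0.0615) and Mmp14 (0.0719). The mean of Tm7sf2 was -0.31 without that pair, so most of its fall lies there, while the means of Cxcl10, Ccl2 and Mmp14 were 0.99, 0.66 and 0.60. Without replicate 6 the 3-week count was 1205 genes, and without replicates 1 and 2 together, an alternative added after the data were seen, it was 1178.

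**Figure D2:**
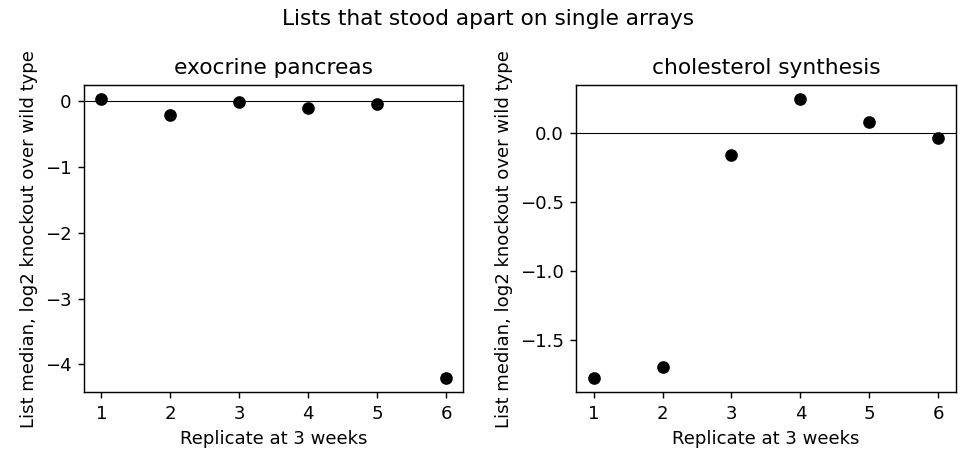
Median log2 ratio of knockout over wild type of the exocrine pancreas list (left) and the cholesterol synthesis list (right) on each of the 6 arrays at 3 weeks, by replicate number. Replicate 6 stands at -4.21 for the pancreas list, and replicates 1 and 2 at -1.78 and -1.70 for the cholesterol list.

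At 6 weeks the same contrast gave more calls. Ifi27l2b and Anxa5 led the rises (3.36 ± 0.43 and 3.28 ± 0.40, adjusted p = 5.72e-11 and 5.72e-11), followed by Klra8 (2.85 ± 0.24), Lcn2 (2.83 ± 0.41), Ly6e (2.76 ± 0.40), Plet1 (2.56 ± 0.49), Cib3 (2.45 ± 0.59) and Tpbpa (2.38 ± 0.44), each positive on 6 of 6 arrays. Klra8 encodes a natural killer cell receptor. Cyp4a31 fell most (-3.54 ± 0.79, adjusted p = 3.05e-07), with Upp2 (-2.75 ± 0.46), Cyp2c38 (-2.68 ± 0.74), Cyp4a14 (-2.58 ± 0.71), Ces1e (-2.13 ± 0.31) and Cyp2c37 (-2.12 ± 0.36) next, all negative on 6 of 6 arrays. Hsd3b5, a steroid-reducing enzyme of male mouse liver, and the methyltransferase Inmt fell as well (-2.08 ± 1.12 and -2.05 ± 0.39).

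Among 34 extracellular matrix genes, 24 rose, 1 fell and 9 did not pass (27 up and 1 down adjusted over the list alone, camera adjusted p = 1.46e-16). Col3a1 (1.94 ± 0.57), Mgp (1.66 ± 0.39) and Col1a2 (1.44 ± 0.37) rose. Among 21 matrix remodelling genes, 9 rose, 1 fell and 11 did not pass (10 up and 2 down adjusted over the list alone, camera adjusted p = 0.00409). The falls became 2 without replicate 2. Serpinh1 (1.15 ± 0.45), the macrophage elastase Mmp12 (1.13 ± 0.33) and the protease inhibitor Timp1 (0.66 ± 0.20) rose. Among 22 stellate cell and myofibroblast genes, 13 rose, 1 fell and 8 did not pass (14 up and 1 down adjusted over the list alone, camera adjusted p = 2.64e-07). Vim (1.49 ± 0.58), Pdgfrb (0.99 ± 0.34) and Des (0.34 ± 0.11) rose. Among 23 cholangiocyte genes, 12 rose, 0 fell and 11 did not pass (12 up and 0 down adjusted over the list alone, camera adjusted p = 2.14e-07, adjusted p = 0.0503 with an estimated correlation). Krt23 (2.09 ± 0.48), Cdh1 (1.61 ± 0.33) and Epcam (0.84 ± 0.23) were examples. Among 27 macrophage genes, 22 rose, 0 fell and 5 did not pass (25 up and 0 down adjusted over the list alone, camera adjusted p = 1.07e-16). Lyz2 (1.96 ± 0.33), Mpeg1 (1.34 ± 0.17) and Lgals3 (1.15 ± 0.35) were among them. Among 7 MHC class II genes, 4 rose, 0 fell and 3 did not pass (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.12 with an estimated correlation). Cd74 (1.21 ± 0.54) and H2-Ab1 (0.87 ± 0.30) rose. Among 31 chemokine and cytokine genes, 14 rose, 4 fell and 13 did not pass (16 up and 5 down adjusted over the list alone, camera adjusted p = 0.00478, adjusted p = 0.20 with an estimated correlation). The rises became 9 without replicate 5, and the falls 2 without replicate 3 or 6. Ccl6 (0.91 ± 0.29) and Cxcl16 (0.55 ± 0.22) rose and Cxcl13 (-0.24 ± 0.13) fell. Among 21 lysosome genes, 5 rose, 0 fell and 16 did not pass (5 up and 0 down adjusted over the list alone, camera adjusted p = 0.00805). Lgmn (0.63 ± 0.32) and Npc2 (0.36 ± 0.31) rose. Among 36 cell cycle genes, 23 rose, 1 fell and 12 did not pass (26 up and 1 down adjusted over the list alone, camera adjusted p = 1.23e-11, adjusted p = 0.0836 with an estimated correlation). Mcm6 (1.56 ± 0.63), Mcm3 (1.40 ± 0.80) and Stmn1 (1.24 ± 0.41) rose; Mcm6 and Mcm3 belong to the replicative helicase. Among 15 oncofetal and tumour-associated genes, 6 rose, 0 fell and 9 did not pass (6 up and 0 down adjusted over the list alone, camera adjusted p = 3.09e-05, adjusted p = 0.0530 with an estimated correlation). Tff3 (2.36 ± 0.25), Ly6d (1.39 ± 0.29) and Golm1 (0.72 ± 0.15) rose. Tested by single features, Golm1 stood at 1.16 on the feature with its smallest p, so the rest of its signal was lower than the average given. Among 24 hepatocyte genes, 0 rose, 8 fell and 16 did not pass (0 up and 11 down adjusted over the list alone, camera adjusted p = 0.00243, adjusted p = 0.13 with an estimated correlation). Arg1 (-1.03 ± 0.28) and Apoa2 (-0.72 ± 0.50) fell. The falls became 5 without replicate 4 or 5.

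Among 18 bile acid synthesis and regulation genes, 1 rose, 10 fell and 7 did not pass (1 up and 10 down adjusted over the list alone, camera adjusted p = 2.06e-05). Cyp7b1 (-1.19 ± 1.25), Cyp27a1 (-0.88 ± 0.16), Nr0b2 (-0.87 ± 0.30) and Klb (-0.56 ± 0.18) fell; Nr0b2 is a nuclear receptor that represses bile acid synthesis and Klb the coreceptor for fibroblast growth factor signals. Among 24 fatty acid oxidation genes, 1 rose, 16 fell and 7 did not pass (1 up and 17 down adjusted over the list alone, camera adjusted p = 2.03e-11). Cyp4a14, Acot1 (-1.77 ± 0.39), Ehhadh (-1.11 ± 0.33) and Cpt2 (-0.81 ± 0.16) fell. Among 21 phase I metabolism genes, 1 rose, 11 fell and 9 did not pass (2 up and 13 down adjusted over the list alone, camera adjusted p = 4.82e-08). Cyp2c38, Cyp2c37, Cyp2e1 (-1.60 ± 0.26) and Cyp2c39 (-1.24 ± 0.24) fell. Among 29 Abcb4 neighbour (chromosome 5) genes, 8 rose, 1 fell and 20 did not pass (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.0304, adjusted p = 0.26 with an estimated correlation). The list no longer passed without replicate 5 (adjusted p = 0.11). The fatty acid translocase Cd36 was 1 of the rises (1.16 ± 0.33). Lists without a camera call at 6 weeks were neutrophil (adjusted p = 0.70, median -0.01 but -0.03 without replicate 5 and 0.00 without replicate 1), lymphocyte (adjusted p = 0.11, median 0.05 but 0.03 without replicate 2), endothelial (adjusted p = 0.36, median 0.02 but -0.04 without replicate 2 and 0.09 without replicate 6), acute phase (adjusted p = 0.24, median 0.09 but 0.18 without replicate 2), hepatobiliary transporter (adjusted p = 0.76, median -0.02 but -0.05 without replicate 5 and 0.00 without replicate 2), cholesterol synthesis (adjusted p = 0.75, median 0.02 but -0.09 without replicate 5 and 0.06 without replicate 2), fatty acid synthesis (adjusted p = 0.27, median -0.14 but -0.05 without replicate 3), phase II and antioxidant (adjusted p = 0.87, median 0.04 but 0.01 without replicate 4 and 0.06 without replicate 6), male-biased liver (adjusted p = 0.34, median -0.20 but -0.30 without replicate 6 and -0.12 without replicate 2), female-biased liver (adjusted p = 0.36, median -0.10 but -0.16 without replicate 5 and -0.05 without replicate 1), interferon-induced (adjusted p = 0.0802, passing at 0.0423 and 0.0460 without replicate 2 or 3, median 0.11 but 0.05 without replicate 5 and 0.18 without replicate 3), endoplasmic reticulum stress (adjusted p = 0.87, median 0.03 but -0.06 without replicate 6), erythroid (adjusted p = 0.29, median -0.14 but -0.24 without replicate 4 and -0.07 without replicate 3), exocrine pancreas (adjusted p = 0.82, median -0.08 but -0.13 without replicate 4 and -0.05 without replicate 1) and adipose (adjusted p = 0.74, median -0.09 but -0.15 without replicate 3 and 0.00 without replicate 5). By fry lymphocyte (0.00171) and interferon-induced (0.0141) passed among them, with the adjusted p given. Leaving out 1 array changed the sign of the medians of neutrophil, endothelial, hepatobiliary transporter, cholesterol synthesis and endoplasmic reticulum stress. Single members of these lists still passed: the basolateral exporter Abcc3 rose (1.02 ± 0.38) and the bile salt uptake carrier Slc10a1 fell (-0.56 ± 0.21), Gstm3 rose (1.22 ± 0.25) and Gstt3 fell (-1.91 ± 0.73).

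At 9 weeks Anxa5 and Lcn2 had the largest rises, 3.55 ± 0.63 and 3.38 ± 0.83 (adjusted p = 1.61e-11 and 9.91e-06). Ifi27l2b, Ly6e, lysozyme Lyz2, the calcium-binding S100a11, Klra8 and the annexin Anxa2 followed with 3.24 ± 0.49, 2.85 ± 0.41, 2.45 ± 0.54, 2.42 ± 0.58, 2.39 ± 0.82 and 2.39 ± 0.65, each positive on 6 of 6 arrays. The largest falls were those of Hsd3b5 and Hsd3b4, both of the Hsd3b steroid dehydrogenase family (-3.81 ± 0.63 and -3.76 ± 0.60, adjusted p = 2.77e-09 and 9.76e-09). Cyp7b1, an oxysterol hydroxylase, had a mean of -2.90 ± 0.97 and the fatty acid elongase Elovl3 one of -2.76 ± 0.57. Mup5, a major urinary protein, fell (-2.23 ± 2.27), but not past the threshold without replicate 3, with scaled arrays or without the dye term (adjusted p = 0.0524, 0.0591 and 0.0785). Mcm10 (-1.98 ± 0.35), Tas2r140 (-1.88 ± 0.64) and Cyp2c38 (-1.84 ± 0.95) completed the 8 largest falls.

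Extracellular matrix genes numbered 34, of which 29 rose, 1 fell and 4 did not pass (30 up and 1 down adjusted over the list alone, camera adjusted p = 2.99e-21). Col3a1 (2.29 ± 0.52), Mgp (2.29 ± 0.45) and Col1a2 (1.69 ± 0.34) were examples of the rises. Matrix remodelling genes numbered 21, of which 9 rose, 0 fell and 12 did not pass (9 up and 0 down adjusted over the list alone, camera adjusted p = 4.99e-04). Serpinh1 (1.12 ± 0.42), Timp3 (0.82 ± 0.41) and Plat (0.62 ± 0.23) rose. Stellate cell and myofibroblast genes numbered 22, of which 14 rose, 1 fell and 7 did not pass (16 up and 1 down adjusted over the list alone, camera adjusted p = 3.96e-08). Tgfbi (1.25 ± 0.37), Pdgfrb (1.03 ± 0.48) and Pdgfra (0.71 ± 0.31) rose. Cholangiocyte genes numbered 23, of which 13 rose, 0 fell and 10 did not pass (13 up and 1 down adjusted over the list alone, camera adjusted p = 8.42e-10). Krt23 (1.74 ± 0.55), Epcam (1.23 ± 0.28) and Krt19 (0.86 ± 0.25) rose. Macrophage genes numbered 27, of which 22 rose, 0 fell and 5 did not pass (25 up and 0 down adjusted over the list alone, camera adjusted p = 3.13e-19). Ctss (1.51 ± 0.45) and C1qb (1.00 ± 0.30) rose. MHC class II genes numbered 7, of which 4 rose, 0 fell and 3 did not pass (4 up and 0 down adjusted over the list alone, camera adjusted p = 2.05e-04). Cd74 (1.90 ± 0.56), H2-Aa (1.77 ± 0.88) and H2-Ab1 (1.22 ± 0.39) rose. Chemokine and cytokine genes numbered 31, of which 12 rose, 3 fell and 16 did not pass (12 up and 4 down adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.17 with an estimated correlation). Ccl20 (1.47 ± 1.03) and Ccl2 (1.35 ± 0.63) rose. Replicate 2 of 9 weeks, whose deposited values had the largest SD of the 24 arrays (0.435), stood apart with list medians of 1.49 for MHC class II, against 0.46 to 0.81 on the others, and 0.29 for chemokines and cytokines, against 0.05 to 0.14. Both lists passed the camera test with any 1 array of the week left out, the MHC class II median being 0.57 without replicate 2. Lymphocyte genes numbered 24, of which 5 rose, 2 fell and 17 did not pass (5 up and 3 down adjusted over the list alone, camera adjusted p = 0.0376, adjusted p = 0.11 with an estimated correlation). Ltb (1.05 ± 0.43) and Coro1a (0.71 ± 0.11) rose. The list no longer passed without replicate 3 or 5 (adjusted p = 0.0621 and 0.0578). Endothelial genes numbered 17, of which 3 rose, 0 fell and 14 did not pass (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.22 with an estimated correlation). The list no longer passed without replicate 3 (adjusted p = 0.0515). Interferon-induced genes numbered 20, of which 9 rose, 2 fell and 9 did not pass (10 up and 2 down adjusted over the list alone, camera adjusted p = 0.00319, adjusted p = 0.13 with an estimated correlation). The rises became 5 without replicate 5, and the falls 1 without replicate 5. Bst2 (0.92 ± 0.20) and Psmb8 (0.89 ± 0.24) rose and Rsad2 (-0.20 ± 0.10) fell. Lysosome genes numbered 21, of which 9 rose, 0 fell and 12 did not pass (11 up and 1 down adjusted over the list alone, camera adjusted p = 1.39e-05). Npc2 (0.69 ± 0.21) and Glb1 (0.49 ± 0.24) rose. Cell cycle genes numbered 36, of which 13 rose, 1 fell and 22 did not pass (19 up and 2 down adjusted over the list alone, camera adjusted p = 6.97e-06, adjusted p = 0.24 with an estimated correlation). The rises became 8 without replicate 2, 4 or 5, and the falls 2 without replicate 4. The cyclin Ccnd1 (1.63 ± 0.40) and Stmn1 (1.25 ± 0.51) rose, and Kif20a, a mitotic kinesin, fell (-0.66 ± 0.52), though not past the threshold with the week fitted on its own (adjusted p = 0.0604). Oncofetal and tumour-associated genes numbered 15, of which 7 rose, 0 fell and 8 did not pass (7 up and 0 down adjusted over the list alone, camera adjusted p = 1.25e-04, adjusted p = 0.0685 with an estimated correlation). Tff3 (2.09 ± 0.88) and Ly6d (1.85 ± 0.51) rose. Hepatocyte genes numbered 24, of which 1 rose, 9 fell and 14 did not pass (1 up and 10 down adjusted over the list alone, camera adjusted p = 0.00936, adjusted p = 0.20 with an estimated correlation). The rises became 2 without replicate 2, and the falls 3 without replicate 5 and 5 without replicate 3. Apoa2 fell (-0.50 ± 0.21) and Trf rose (1.20 ± 0.37) on the arrays that carried these other changes.

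Bile acid synthesis and regulation genes numbered 18, of which 0 rose, 10 fell and 8 did not pass (0 up and 11 down adjusted over the list alone, camera adjusted p = 1.21e-05). The falls became 5 without replicate 4. Besides Cyp7b1, Cyp27a1 (-0.88 ± 0.19) and Slc27a5 (-0.72 ± 0.20) fell. Fatty acid oxidation genes numbered 24, of which 2 rose, 10 fell and 12 did not pass (2 up and 14 down adjusted over the list alone, camera adjusted p = 1.47e-04, adjusted p = 0.17 with an estimated correlation). Acot1 (-0.99 ± 0.42) and Cpt2 (-0.54 ± 0.27) fell, while Pdk4, which inhibits pyruvate oxidation, rose (1.40 ± 0.81). Phase I metabolism genes numbered 21, of which 4 rose, 11 fell and 6 did not pass (4 up and 12 down adjusted over the list alone, camera adjusted p = 7.46e-04, adjusted p = 0.0893 with an estimated correlation). The rises became 2 without replicate 2. Cyp2c37 (-1.75 ± 0.86) and Cyp2e1 (-1.49 ± 0.45) fell and Cyp3a11 (1.77 ± 0.71) rose. Male-biased liver genes numbered 11, of which 0 rose, 7 fell and 4 did not pass (0 up and 8 down adjusted over the list alone, camera adjusted p = 3.38e-05, adjusted p = 0.0531 with an estimated correlation). Hsd3b5, Elovl3 and Susd4 (-0.99 ± 0.73) fell. Camera made no call at 9 weeks for neutrophil (adjusted p = 0.29, median -0.05), acute phase (adjusted p = 0.28, median 0.16), hepatobiliary transporter (adjusted p = 0.87, median 0.05 but 0.00 without replicate 5), cholesterol synthesis (adjusted p = 0.29, median -0.18 but -0.06 without replicate 5), fatty acid synthesis (adjusted p = 0.84, median 0.09 but 0.01 without replicate 5 and 0.18 without replicate 4), phase II and antioxidant (adjusted p = 0.44, median 0.05 but 0.02 without replicate 2 and 0.11 without replicate 3), female-biased liver (adjusted p = 0.28, median 0.05 but 0.02 without replicate 2 and 0.08 without replicate 1), endoplasmic reticulum stress (adjusted p = 0.59, median -0.10 but -0.16 without replicate 6 and -0.03 without replicate 2), erythroid (adjusted p = 0.40, median -0.04 but -0.16 without replicate 2), exocrine pancreas (adjusted p = 0.85, median -0.07 but -0.13 without replicate 5 and 0.03 without replicate 2), adipose (adjusted p = 0.85, median -0.09) and Abcb4 neighbours on chromosome 5 (adjusted p = 0.13, median 0.01 but 0.00 without replicate 6 and 0.04 without replicate 5). With fry the calls among these were neutrophil (0.0192), female-biased liver (0.00829) and Abcb4 neighbours on chromosome 5 (0.0178), each with its adjusted p. The sign of the median turned when 1 array was left out for hepatobiliary transporter, exocrine pancreas and Abcb4 neighbours on chromosome 5. Among members of the lists, Cyp3a41a (1.55 ± 0.82), Ntrk2 (0.90 ± 0.29) and Abcc3 (1.44 ± 0.72) rose. Of the 2 features of Ntrk2, the one with the smaller p stood at 1.76 when tested singly, so the other was far lower. Slc22a7, an organic anion carrier, and the neutrophil calprotectin subunit S100a9 fell (-1.59 ± 0.38 and -0.80 ± 0.62). S100a9 did not pass with the week fitted on its own (adjusted p = 0.0545).

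At 20 weeks Ifi27l2b and Anxa5 again had the largest rises (3.46 ± 0.49 and 3.25 ± 0.35, adjusted p = 3.89e-11 and 6.84e-11). Lcn2, Ly6e, Klra8, the invariant chain Cd74, the secreted trefoil peptide Tff3 and the fibrillar collagen Col3a1 came next, at 2.67 ± 1.06, 2.42 ± 0.45, 2.36 ± 0.31, 2.01 ± 0.43, 2.00 ± 0.17 and 1.99 ± 0.45, each positive on 6 of 6 arrays. Cyp2c38 fell most (-3.64 ± 0.49, adjusted p = 8.73e-09). Hsd3b4 and Hsd3b5 stood at -2.60 ± 0.67 and -2.57 ± 0.49, and Cyp2c37 (-2.12 ± 0.59), Moxd1 (-1.93 ± 0.66), Sdr9c7 (-1.79 ± 0.17), Ces1f (-1.76 ± 0.64) and Ces1e (-1.69 ± 0.34) were the other falls of this size, negative on 6 of 6 arrays.

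In the extracellular matrix list, 23 of 34 genes rose, 0 fell and 11 did not pass (26 up and 1 down adjusted over the list alone, camera adjusted p = 4.78e-17). Lum (1.93 ± 0.71), Mgp (1.68 ± 0.65) and Col1a2 (1.55 ± 0.34) rose. In the matrix remodelling list, 9 of 21 genes rose, 2 fell and 10 did not pass (11 up and 2 down adjusted over the list alone, camera adjusted p = 8.56e-05). Mmp7 (0.75 ± 0.41) and Mmp2 (0.67 ± 0.23) rose. The falls became 1 without replicate 1, 2, 3 or 6. In the stellate cell and myofibroblast list, 12 of 22 genes rose, 1 fell and 9 did not pass (12 up and 1 down adjusted over the list alone, camera adjusted p = 2.92e-07). Vim (1.73 ± 0.31), Pdgfrb (1.04 ± 0.34) and Gsn (0.83 ± 0.28) rose. In the cholangiocyte list, 12 of 23 genes rose, 0 fell and 11 did not pass (12 up and 0 down adjusted over the list alone, camera adjusted p = 4.51e-10). Epcam (0.97 ± 0.50), Tspan8 (0.83 ± 0.40) and Krt19 (0.78 ± 0.37) rose. In the macrophage list, 20 of 27 genes rose, 0 fell and 7 did not pass (22 up and 1 down adjusted over the list alone, camera adjusted p = 8.36e-15). Lyz2 (1.80 ± 0.33), Mpeg1 (1.21 ± 0.27) and Fcgr3 (0.68 ± 0.18) rose. In the MHC class II list, 4 of 7 genes rose, 0 fell and 3 did not pass (4 up and 1 down adjusted over the list alone, camera adjusted p = 4.36e-04). H2-Aa (1.67 ± 0.31) and H2-Ab1 (1.15 ± 0.20) rose. In the chemokine and cytokine list, 12 of 31 genes rose, 0 fell and 19 did not pass (13 up and 2 down adjusted over the list alone, camera adjusted p = 5.84e-04, adjusted p = 0.12 with an estimated correlation). Ccl2 (0.87 ± 0.42), Cxcl16 (0.50 ± 0.26) and Ccl5 (0.46 ± 0.26) rose. In the interferon-induced list, 7 of 20 genes rose, 0 fell and 13 did not pass (9 up and 1 down adjusted over the list alone, camera adjusted p = 5.84e-04, adjusted p = 0.0776 with an estimated correlation). Psmb8 (0.88 ± 0.29) and Bst2 (0.84 ± 0.31) rose. The rises became 4 without replicate 1, 5 or 6. In the lysosome list, 6 of 21 genes rose, 0 fell and 15 did not pass (10 up and 0 down adjusted over the list alone, camera adjusted p = 4.26e-04). Npc2 (0.74 ± 0.10) and Glb1 (0.49 ± 0.34) rose. In the oncofetal and tumour-associated list, 5 of 15 genes rose, 0 fell and 10 did not pass (6 up and 0 down adjusted over the list alone, camera adjusted p = 4.26e-04, adjusted p = 0.0893 with an estimated correlation). Cd63 (0.77 ± 0.10) and Golm1 (0.54 ± 0.14) rose. Golm1 stood at 1.01 on the feature with its smallest p when features were tested singly, and lower on the rest. In the bile acid synthesis and regulation list, 0 of 18 genes rose, 3 fell and 15 did not pass (0 up and 4 down adjusted over the list alone, camera adjusted p = 0.00281). Cyp27a1 fell (-0.53 ± 0.16), and Cyp7b1 (-1.12 ± 0.44) fell, but not past the threshold without replicate 1 or 3 or with the closest pair averaged (adjusted p = 0.0502, 0.0725 and 0.0607). In the phase I metabolism list, 4 of 21 genes rose, 10 fell and 7 did not pass (4 up and 10 down adjusted over the list alone, camera adjusted p = 4.46e-04, adjusted p = 0.0776 with an estimated correlation). Cyp2e1 fell (-1.05 ± 0.49) and Aldh3a2 rose (1.20 ± 0.15). In the male-biased liver list, 1 of 11 genes rose, 3 fell and 7 did not pass (1 up and 3 down adjusted over the list alone, camera adjusted p = 0.00936, adjusted p = 0.21 with an estimated correlation). Hsd3b5, Elovl3 (-1.56 ± 0.45) and Susd4 (-1.35 ± 0.29) fell. The lists without a camera call at 20 weeks were neutrophil (adjusted p = 0.90, median 0.00 but -0.01 without replicate 1 and 0.02 without replicate 4), lymphocyte (adjusted p = 0.11, passing at 0.0402 without replicate 3, median 0.02 but 0.05 without replicate 3), endothelial (adjusted p = 0.98, median 0.00 but -0.06 without replicate 3 and 0.03 without replicate 6), acute phase (adjusted p = 0.78, median -0.01 but -0.30 without replicate 4 and 0.20 without replicate 3), hepatobiliary transporter (adjusted p = 0.14, median -0.17), cholesterol synthesis (adjusted p = 0.25, passing at 0.0224 without replicate 5, median -0.07 but -0.20 without replicate 5 and 0.00 without replicate 2), fatty acid synthesis (adjusted p = 0.25, median -0.12 but -0.20 without replicate 5 and 0.04 without replicate 4), fatty acid oxidation (adjusted p = 0.0985, passing at 0.0393 and 0.0348 without replicate 1 or 3, median -0.10 but -0.05 without replicate 5), phase II and antioxidant (adjusted p = 0.61, median 0.08 but 0.05 without replicate 2), female-biased liver (adjusted p = 0.17, median 0.03 but -0.01 without replicate 5 and 0.05 without replicate 3), cell cycle (adjusted p = 0.0528, passing at 0.0250 without replicate 6, median 0.11 but 0.07 without replicate 2), hepatocyte (adjusted p = 0.0799, passing at 0.0394 and 0.0306 without replicate 1 or 3, median -0.20), endoplasmic reticulum stress (adjusted p = 0.85, median 0.11 but -0.06 without replicate 4 and 0.23 without replicate 2), erythroid (adjusted p = 0.45, median -0.08 but -0.18 without replicate 1 and 0.00 without replicate 6), exocrine pancreas (adjusted p = 0.31, median -0.20), adipose (adjusted p = 0.31, median -0.13 but -0.07 without replicate 6) and Abcb4 neighbours on chromosome 5 (adjusted p = 0.0852, passing at 0.0390 without replicate 3, median 0.05 but 0.02 without replicate 2). In the same group fry called lymphocyte (6.25e-04), hepatobiliary transporter (0.00302), female-biased liver (0.00405), adipose (0.0356) and Abcb4 neighbours on chromosome 5 (0.0242), with the adjusted p in brackets. Without replicate 4 the adjusted p of the acute phase list was 0.0569. The sign of its median is not settled, and 1 array also turned the sign of the medians of neutrophil, endothelial, fatty acid synthesis, female-biased liver, endoplasmic reticulum stress and erythroid. Members that rose singly were Ccnd1 (1.56 ± 0.33), Stmn1 (0.94 ± 0.40), Cyp3a41a (1.93 ± 0.95), Cyp2a4 (1.15 ± 0.31), Abcc3 (1.19 ± 0.47), Cd34 (0.70 ± 0.31) and Jchain (0.66 ± 0.32), and Apcs (-1.63 ± 0.87) and Slc22a7 (-1.59 ± 0.69) fell.

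**Figure D3:**
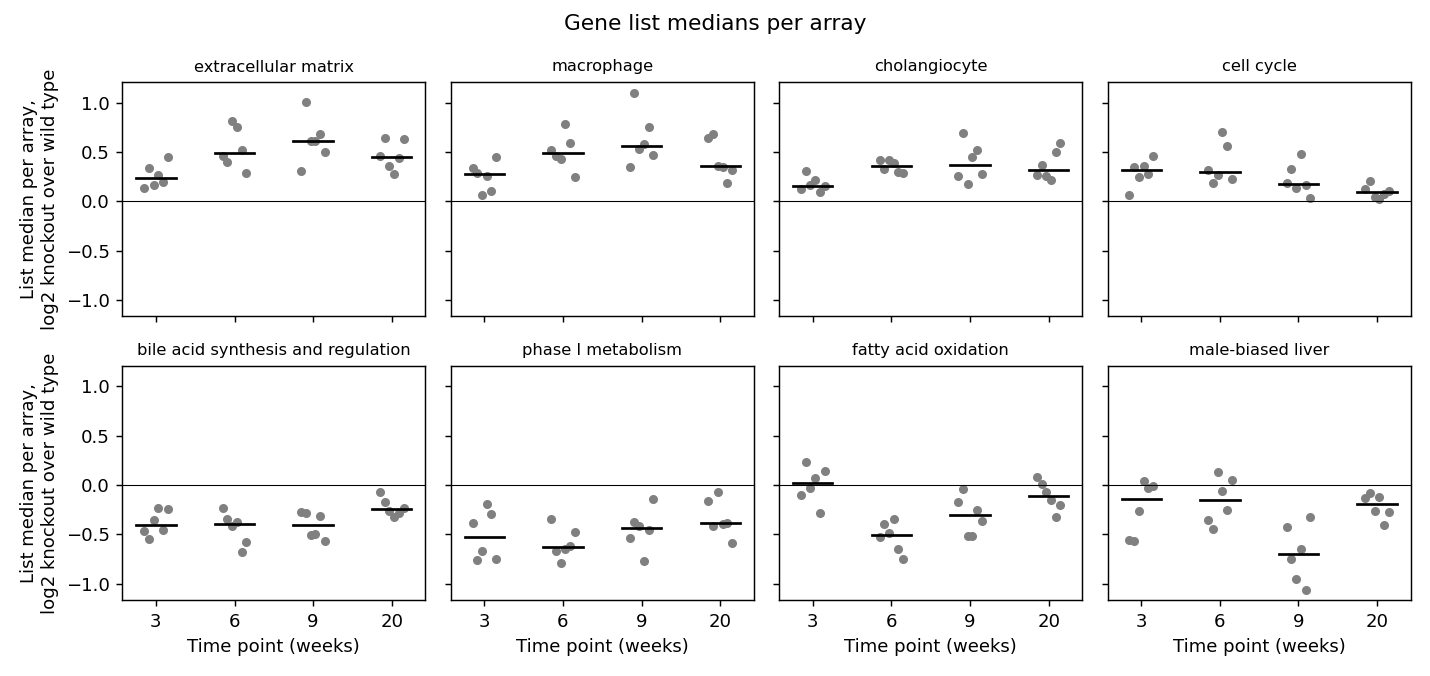
Median log2 ratio of knockout over wild type over the genes of 8 lists on each array (grey points) at 3, 6, 9 and 20 weeks, with the median of the 6 arrays of a week as a bar, on one vertical scale for all panels. The extracellular matrix and macrophage lists lie above 0 and the bile acid and phase I lists below 0 on all 24 arrays.

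The time course then asked whether the difference between genotypes itself changed with age. Hsd3b5 and Hsd3b4, of the Hsd3b family, Cyp7b1 and Elovl3 did not pass at 3 weeks and were far lower in the knockout at 9 weeks. Signal over background is not used here, so a ratio near 0 was not told from weak signal in both genotypes. At 3, 6, 9 and 20 weeks Hsd3b5 had means of -0.20 ± 0.29, -2.08 ± 1.12, -3.81 ± 0.63 and -2.57 ± 0.49, Hsd3b4 of -0.29 ± 0.44, -1.99 ± 1.19, -3.76 ± 0.60 and -2.60 ± 0.67, Cyp7b1 of -0.09 ± 0.22, -1.19 ± 1.25, -2.90 ± 0.97 and -1.12 ± 0.44 and Elovl3 of -0.26 ± 0.32, -0.96 ± 0.60, -2.76 ± 0.57 and -1.56 ± 0.45. Cyp2a4 went from -2.78 ± 1.07 at 3 weeks through -0.79 ± 0.85 and 0.33 ± 0.58, which did not pass, to 1.15 ± 0.31 at 20 weeks. H19 and Eif4ebp3 passed at 3 weeks alone: the means of H19 were 3.08 ± 2.37, 0.01 ± 0.18, -0.33 ± 0.26 and -0.31 ± 0.38, those of Eif4ebp3 -2.84 ± 1.28, -0.17 ± 0.76, -0.44 ± 0.92 and -0.43 ± 0.79. The fit shares 1 residual spread per gene over all weeks, so the larger SD of H19 at 3 weeks is averaged with smaller ones. Its 3-week call ended with that week fitted on its own (moderated test, adjusted p = 0.15). The F test of H19 rests on the same shared spread. Serpina6, the corticosteroid-binding globulin, was higher at 3 weeks and lower at 6 weeks (1.44 ± 0.45, -1.15 ± 0.51, -0.15 ± 0.41 and 0.20 ± 0.24). Cyp4a31 (-1.48 ± 1.35, -3.54 ± 0.79, -1.54 ± 0.50 and -1.07 ± 0.73) and Cyp2c38 (-0.91 ± 1.04, -2.68 ± 0.74, -1.84 ± 0.95 and -3.64 ± 0.49) fell at every week. At 3 weeks the SD of Cyp2c38 exceeded the size of its mean. The naming rule did not take either gene at 3 weeks, so these 3-week values were not checked under the alternatives. The adjusted p of the moderated F test was 8.20e-05 for Hsd3b5, 2.42e-04 for Hsd3b4, 0.00413 for Cyp7b1, 1.06e-04 for Elovl3, 8.20e-05 for Cyp2a4, 0.00637 for H19, 0.00865 for Eif4ebp3, 2.45e-05 for Serpina6, 0.0109 for Cyp4a31 and 7.59e-04 for Cyp2c38. By that test 1060 genes differed between weeks.

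**Figure D4:**
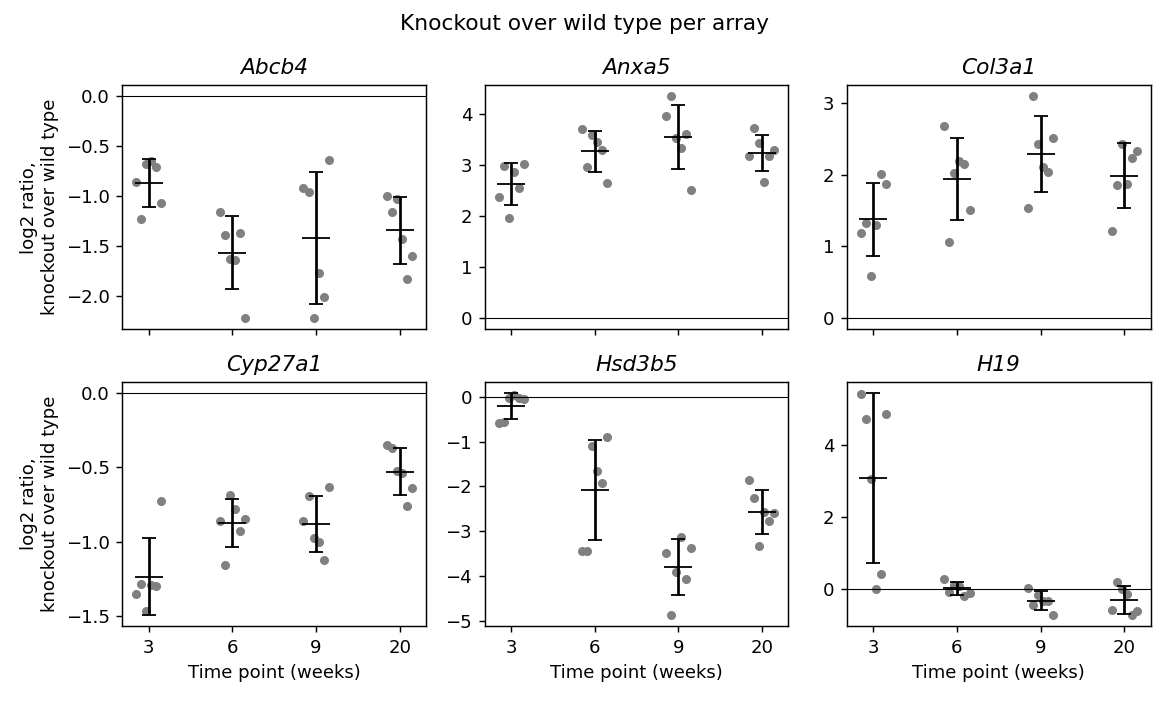
Log2 ratio of knockout over wild type on each array (grey points) for 6 genes at 3, 6, 9 and 20 weeks, with the mean (long bar) and SD (error bar) of 6 arrays per week; the vertical scales differ between genes. Abcb4 lies below 0 and Anxa5 above 0 on all 24 arrays, and Hsd3b5 goes from a mean of -0.20 at 3 weeks to -3.81 at 9 weeks.

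Against 3 weeks, the ratio of 271 genes differed at 6 weeks (145 higher and 126 lower than at 3 weeks), of 765 at 9 weeks (335 and 430) and of 953 at 20 weeks (631 and 322). These comparisons share the 3-week arrays, so their counts are not independent. Averaging the closest pair of arrays of opposite dye orientation in each week lowered these counts to 103, 389 and 376 and that of the F test to 367, and array weights raised the last to 1615. Scaling the arrays to a common spread gave 1475 genes for 20 against 3 weeks, fitting only the weeks compared gave 323 for 9 against 3 weeks, and leaving out replicates 1 and 2 of 3 weeks together gave 439 for 6 against 3 weeks. Without replicate 3 of 3 weeks the F test called 685 genes, the 9-week difference 449 and the 20-week difference 503. Other single arrays that moved a difference were replicate 4 of 3 weeks (506 at 9 weeks), replicates 4 and 5 of 6 weeks (179 and 165 at 6 weeks), replicate 5 of 9 weeks (442 at 9 weeks) and replicates 1 and 2 of 20 weeks (504 and 612 at 20 weeks). Averaged over the 4 weeks, 8002 genes passed, 3893 higher and 4109 lower in the knockout. Across all genes, which are not independent replicates, the weekly means correlated with r of 0.62 (3 and 6 weeks), 0.59 (3 and 9), 0.37 (3 and 20), 0.84 (6 and 9), 0.64 (6 and 20) and 0.74 (9 and 20).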

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

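The tests of the pancreas and cholesterol patterns were chosen after those results were seen; so were the splits with the closest pair averaged, while the splits of single arrays were not. Single arrays were compared with the others of their week by the gap to the nearest array over the range, for the named genes and the 30 lists. Of 383 such checks 19 passed the 95% limit, where chance alone gives about 1 in 20 (19.2). The genes checked are those named, a choice made after their values were seen; over all 438 gene and week results that the naming rule allows, 20 passed the limit, where chance gives 21.9, and 7 of the 20 belong to results not named. The rule itself takes genes past the threshold, and its largest changes have 1 sign on every array, which can remove genes with a stray array. The share of 1 in 20 is therefore only a rough guide. Results on the same array are not independent either, so a total near that of chance does not show that each case is chance.

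At 3 weeks the exocrine pancreas list stood apart on replicate 6, with a median of -4.21. Cela2a read -5.90, Pnliprp1 -5.01 and Prss2 -4.57 there, and 11 of the 11 measured members lay below -1, against at most 1 on any other array. A dye effect alike on all arrays of that orientation is argued against, since the lowest list median on the 9 such arrays of the other weeks was -0.26. Replicates 3 and 4 of 3 weeks share the orientation, and their lowest median of -0.10 argues against a dye effect confined to that week. The lowest on the other 5 arrays of 3 weeks was -0.20, against a knockout effect alike in all mice; the array was picked for this difference, so these values exclude but add no support to another cause. Pancreatic tissue in the wild type liver sample of that array may account for the pattern, as a hypothesis; which of these genes liver transcribes at a low level was not tested, and no member stands in another list. Amy2a5 is an exception. It read -3.36 on replicate 6 and from -4.15 to -0.76 on the other 5 arrays of the week, so its fall is not confined to replicate 6. In all, 3 members were negative on all 6 arrays. Besides Amy2a5 these were Cela2a and Cpb1, which on the other 5 arrays read -0.71 to -0.28 and -0.20 to -0.01.

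The cholesterol synthesis list was low on replicates 1 and 2 at 3 weeks, at -1.78 and -1.70. On the 9 arrays of the other weeks with the same dye orientation the lowest list median was -0.65, which argues against a dye effect alike on all such arrays. One confined to 3 weeks stays open, since replicate 5, at 0.076, is the only other array of that orientation in the week. Across the values without centring, with a common spread or with quantile normalization, the highest median of the pair was -1.29, which argues against these steps. The lowest median of the other 4 arrays was -0.16, which argues against a knockout effect alike in all mice, though the pair was picked for this difference. Differences between single mice, such as feeding state, litter or sampling time, and a sharing of mice between the pair stay open as untested.

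The other arrays that stood apart are given as values. At 3 weeks Cdh1 read 2.04 and Cyp27a1 -0.72 on replicate 6, and Tff3 1.84 on replicate 2. At 6 weeks Vim read 0.40 and the matrix remodelling list median 0.25 on replicate 2, and the neutrophil list median -0.18 on replicate 3. Of the 19 cases 7 fell on replicate 2 of 9 weeks, the most on any array, followed by 3 on replicate 6 of 3 weeks; the deposited values of that 9-week array had the largest SD of all arrays (0.435), and the cause was not tested. This array held Pdgfra at 1.32, Ctss at 2.40, Slc22a7 at -2.36 and Cyp3a41a at 3.10, with list medians of 0.29 for chemokines and cytokines, 1.49 for MHC class II and 0.20 for the Abcb4 neighbours, and replicate 5 held S100a9 at -2.03. At 20 weeks Lcn2 read 4.68 on replicate 4, Lyz2 1.17 and Mpeg1 1.71 on replicate 1, and Cyp7b1 -1.98 on replicate 3.

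The difference between genotypes itself changed with age for 1060 genes by the F test, and against 3 weeks for 271 genes at 6, 765 at 9 and 953 at 20 weeks. The F test's adjusted p was 8.20e-05 for Cyp2a4, 8.20e-05 for Hsd3b5, 2.42e-04 for Hsd3b4, 0.00637 for H19, 0.00413 for Cyp7b1, 7.59e-04 for Cyp2c38, 0.00865 for Eif4ebp3, 2.45e-05 for Serpina6, 1.06e-04 for Elovl3 and 0.0109 for Cyp4a31. For these counts chance assignment was the only explanation tested, and for the single genes none was tested.

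Other assignments of the arrays were fitted to see whether chance gives as many genes. Exchanging knockout and wild type within the 6 arrays of a week makes 32 splits, of which 1, the real one, reached the real count at each week: 1542 against at most 421 at 3 weeks, 4362 against 1211 at 6 weeks, 4444 against 2161 at 9 weeks and 2807 against 257 at 20 weeks. The split that follows dye orientation gave 0, 2, 0 and 0 genes. Its low counts were built in and say nothing on dye effects. The dye term, set by the other weeks, was subtracted there, and the genotype difference widened the spread. With 5 mice per genotype and week, however, 1 array repeats mice and must be exchanged together with its partner, which leaves 16 splits. With the closest pair averaged, 1 of 16 splits reached the real count at each week: 1149 against at most 195 at 3 weeks, 3144 against 1 at 6 weeks, 3512 against 158 at 9 weeks and 2053 against 0 at 20 weeks. These splits are too few for a share under 0.05.

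For the mean over weeks, 1 of 100 drawn splits reached 8002, the next having 2407. Exchanging arrays between weeks, 1 of 100 reached 1060 by the F test (next 9), 1 of 100 reached 271 for 6 against 3 weeks (next 1), 1 of 100 reached 765 for 9 against 3 weeks (next 183) and 1 of 100 reached 953 for 20 against 3 weeks (next 169). With the closest pair averaged, 1 of 100 drawn splits reached 7027 for the mean (next 315), 367 by the F test (next 0), and 103, 389 and 376 for 6, 9 and 20 against 3 weeks (next 51, 68 and 28). Chance assignment is excluded for these 5 counts, with the pairs averaged as well, if the closest pair is the repeated one, which is unsettled.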

How the results depend on the processing

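The fit on features with 1 gene and the one without replicates 1 and 2 of 3 weeks were chosen after the results were seen. None of the 438 gene and week results that the naming rule allows reversed under any alternative run or with any array of its week left out. Much of this was fixed in advance. With 3 arrays per dye orientation, the dye settings, weekly fits, the block, robust empirical Bayes and the stricter threshold leave weekly means unchanged. The largest changes were chosen for 1 sign on all 6 arrays, which leaves little room for a reversal. Features tested singly were compared by the feature with the smallest p of each gene. Of the 438 results 329 stayed past the threshold throughout, and 65 ended when 1 array was left out, of which the text names 2. The largest numbers ended with weeks fitted on their own (71), under an adjusted p of 0.01 (60) or with the closest pair averaged (33); 25 ended without replicates 1 and 2 of 3 weeks, 14 with scaled arrays, 11 without the dye term, 3 with array weights, and 2 each with quantile normalization, a dye term per week and the sample number as a block. Counts stayed within 1.5 times without centring, with quantile normalization, with either dye setting, with features tested singly, with robust empirical Bayes and with features of 1 gene. Weekly fits give no F or mean value, and single features no list value. The filters on missing values test nothing, as no value is missing. Signal over background is not used here, so its limit on weak genes is unknown.

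Scaling arrays to a common spread gave 2480 genes at 3 weeks and 1475 for 20 against 3 weeks. Weeks fitted on their own gave 525 at 3 weeks, 2286 at 9 weeks and 323 for 9 against 3 weeks. These fits have fewer arrays behind each spread and share no spread with the weeks left out, unlike the main fit. The SD of a gene can differ between weeks, as for Lcn2 with 1.79 at 3 weeks and 0.41 at 6 weeks. Array weights gave 1615 by the F test. The closest pair averaged, which leaves fewer replicates, gave 367 by the F test and 103, 389 and 376 for 6, 9 and 20 against 3 weeks; these pairs correlated at 0.65, 0.53, 0.74 and 0.62 at 3, 6, 9 and 20 weeks, the next closest at 0.63, 0.52, 0.59 and 0.61, so the repeated pair stays unsettled. By construction, an adjusted p under 0.01 gave fewer: 897, 2322, 2744 and 1375 at 3, 6, 9 and 20 weeks, 328 by the F test and 99, 297 and 306 for the differences from 3 weeks. Of 64 list calls 32 passed with an estimated correlation, and fry called 75. Without replicates 1 and 2 of 3 weeks, 6 against 3 weeks gave 439. Unless the construction is named, the cause was not tested.

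Leaving out 1 array at a time gave 1205 to 1799 genes at 3 weeks, 2934 to 4794 at 6, 3293 to 4520 at 9 and 1821 (without replicate 2 of 20 weeks) to 3322 at 20 weeks. The F test gave 685 (without replicate 3 of 3 weeks) to 1416. Against 3 weeks, 6 weeks gave 165 (without replicate 5 of 6 weeks; 179 without replicate 4) to 367, 9 weeks 442 (without its replicate 5; 449 and 506 without replicates 3 and 4 of 3 weeks) to 1003, and 20 weeks 503 (without replicate 3 of 3 weeks; 504 and 612 without its replicates 1 and 2) to 1296. The mean over weeks gave 7482 to 8046 and the lists 62 to 68 calls. Why these arrays move the counts was not tested.

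Sample numbers recur in each week. Of 36 pairs of arrays with 1 number 18 correlated above 0.1 (median r 0.092, lowest -0.36). The median r between arrays of different numbers was -0.0096, and 7 of 24 arrays correlated best with their own number. A pairing by number is therefore neither shown nor excluded, and the main fit does not use one. With the sample number as a block the counts were 1547, 4397, 4401 and 2857 at 3, 6, 9 and 20 weeks, 1119 by the F test, 282, 756 and 992 against 3 weeks, 7973 for the mean and 64 list calls.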

Other observations

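The test on the neighbours of Abcb4 was chosen after the result was seen. The strain label names a 129P2 origin of the targeted allele on an FVB background, so genes beside Abcb4 on chromosome 5 could carry the other strain's DNA, and the list of neighbours had been fixed before the data were examined. On average over the 4 weeks, 13 of 29 measured neighbours passed (44.8%), 10 higher and 3 lower, against 41.4% of the 16474 other named genes. The odds ratio was 1.15 (95% interval 0.51 to 2.56; Fisher's exact test, two-sided, p = 0.71), so a strain effect on the region cannot be told apart from none with this few genes. Steap4, a metalloreductase, averaged 1.10, the fatty acid translocase Cd36 0.91, the calcium-binding Sri 0.40, and the drug exporters Abcb1b and Abcb1a, the closest relatives of Abcb4, 0.33 and 0.27. Cldn12 averaged -0.20. Probes of the Abcb1 genes can bind transcripts of their relatives, so these values are uncertain.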
